A study of Mus musculus with 8 samples.

How the data were processed

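CUT&Tag was carried out on MEL cells, a mouse erythroleukaemia line, with antibodies against the C-terminal domain of the RNA polymerase II subunit Rpb1 phosphorylated on serine 5 (Ser5P) or on serine 2 (Ser2P). In CUT&Tag an antibody tethers a transposase that cuts and tags nearby chromatin. Per the labels, the same number of cells was used for every biological replicate, and 2 replicates were prepared for each antibody from a dCas control line and from a line with knockdown of Myrlin (KD), the transcript of the enhancer 81 kb upstream of Myb. This gave 8 libraries in 4 groups. The labels do not say how the cultures were separated, so p-values measure the spread between these libraries, which may be technical.

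The deposited files were MACS2 peak lists called for each library apart. Per the submitters' processing notes the tools were cutadapt 2.7, Bowtie2 2.3.5, SAMtools 1.9, Picard 2.21.4, deepTools 3.3.1 and MACS2 2.2.7.1, on GRCm38/mm10. Their parameters, and whether a control library entered peak calling, are not given in the sources used here. For every peak the authors deposited a display score, the fold enrichment at the summit over the local background as a ratio, the −log10 p-value, the −log10 q-value and the offset of the summit. The lowest −log10 q in each list lay between 1.30 and 1.31. Fold and p belong to each list and were used only to rank, filter or describe peaks. To order the items named, the smallest of the folds in the marked libraries was taken, which sets folds of different lists side by side. No change between libraries was read from them.

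Peaks on the autosomes, X and Y were used, and 24 to 30 peaks per library on other sequences were left out. Read totals were not used here. MACS2 computes both fold and p from a whole-number summit pileup and a background pileup, so both were solved for each peak, with a tolerance of 0.001 on −log10 p. A solution was found for over 99.9% of peaks in every library. The most frequent background value of a library, taken as the fullest narrow bin on a log scale, served as its relative depth. On simulated peaks 99.94% of pileups were recovered, against 0.18% when the simulated pileup was not a whole number.

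Gene positions came from the RefSeq gene table for GRCm38.p6, whose build matches the files. The genome supplied beside it, NCBIM37, does not match, since peaks lay beyond its ends on several chromosomes, and no coordinate from it was used. The table holds no strand, which was taken by symbol (18392 genes) or synonym (2191 genes) on the same chromosome from GENCODE vM1. Of 21887 protein-coding genes, 20583 received a strand and the other 1304 were left out. The gene 5′ end is the outer end of the table's interval, so a start inside the gene is not seen as a promoter. Exon and intron annotation was not used here.

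Overlapping peaks of the 4 libraries of an antibody were merged into regions, and a library had a region where a peak overlapped it by at least 1 bp. A region or gene was called control-only when both controls and neither KD library had a peak, and KD-only in the reverse case. For genes the window was 1000 bp each side of the 5′ end for Ser5P, and from 1000 bp inside the 5′ end to 3000 bp past the 3′ end for Ser2P. Counts were set beside the other 2 of the 3 ways to split 4 libraries into pairs. With 2 libraries against 2 the exact permutation test cannot give a p under 0.05: its smallest two-sided value is 0.333. Enhancer windows spanned 2000 bp each side of points upstream of the Myb 5′ end. Promoter shares were compared by a two-sided exact permutation test over 70 arrangements. The 16 gene lists were tested with two-sided Fisher's exact tests, for losses among genes marked in both controls and for gains among genes marked in neither, with Benjamini-Hochberg adjustment over the 55 tests with at least 3 members in the background. Genes are not replicates, so such p-values compare these libraries. Intervals on shares of regions are 95% Wilson intervals and cover counting error only.

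Genes were named by a rule: the neighbours of Myb, the 10 called genes per antibody and direction ranking highest by the smaller of the best folds in the 2 marked libraries (predicted genes passed over), up to 4 called members per list, the MLL1 complex members, and 5 regions per antibody and direction. Some genes this rule takes are not reported here. This rule, the lists, the tests and most alternatives were fixed before the data were examined. The alternatives were a −log10 q of at least 5, equal numbers of peaks per library, leaving out each library, other windows and overlaps, and limma on the covered share of each gene window with and without the replicate number as a block. Chosen after seeing the data were a minimum of 200 bp covered for the named genes and the lists, which had been fixed for the gene counts only, binomial thinning of the recovered pileups to the shallowest library, the ratios of the 2 directions, the regions joint to both antibodies, the places of called regions and the rank of the Myb interval.

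On simulated data of 20583 genes with 200 planted presence changes, 82% were called with the Ser5P window and 86% with the Ser2P window, with 0 in the wrong direction. In the same simulation 448 (Ser5P) and 750 (Ser2P) unplanted genes were called, although their chance of a peak was equal in all 4 libraries. That chance was smoothed towards the middle, which adds calls, so these numbers are not an estimate of false calls in the real libraries. They show only that a single gene call can arise without any group difference. Of 500 random lists tested for Ser2P loss, 2.8% gave p under 0.05. Random lists were not tested for gains, so this share does not cover the gain tests. On simulated covered shares, limma called 82.5% of 200 Ser5P genes moved by 80% of the window and 0 of those moved by 40%. For Ser2P it called 85.5% and 48.0%. The steps were added without a bound, so simulated shares could leave the range that a real share can take. These percentages therefore do not give the power for real changes. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.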

Results

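Peaks of phosphorylated RNA polymerase II were mapped in 8 CUT&Tag libraries from MEL cells, 2 for each combination of antibody (Ser5P or Ser2P) and cell line (dCas control or Myrlin KD). Ser5P is placed on polymerase at initiation, and Ser2P accumulates during elongation. The Ser5P lists held 23964 and 25441 peaks in the controls and 21574 and 24509 in the KD libraries. The Ser2P lists held 30286 and 20793 peaks in the controls and 32125 and 29372 in the KD libraries. Relative depth, read as the background pileup, was 0.566 and 0.639 in the Ser5P controls against 0.649 and 0.841 in the KD libraries. For Ser2P it was 0.780 and 0.439 in the controls against 1.12 and 1.03 in the KD libraries, so both Ser2P KD libraries were deeper than both controls. Median peak width for Ser5P was 486 and 497 bp in the controls against 533.5 and 532 bp in the KD libraries. For Ser2P it was 428 and 381 bp against 478 and 479 bp. Peaks were thus wider in every KD library, which raises covered bp across the whole library.

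The first comparison asked whether polymerase at Myb, which encodes a transcription factor of blood progenitors, differed after knockdown of the transcript of its enhancer. At the enhancer 81 kb upstream, the source of Myrlin, Ser5P peaks covered 513 and 237 bp in the controls, 275 bp in KD 1 and 0 bp in KD 2. Over the 5 enhancer windows together, Ser5P peaks covered 2456 ± 34.6 bp in the controls and 1546 ± 296 bp in the KD libraries (SD, n = 2 each). The two-sided exact permutation p was 0.333, the smallest that this test can give with 2 libraries against 2. Ser2P coverage of the same windows was 1763 ± 452 bp in the controls and 1980 ± 426 bp in the KD libraries, a difference smaller than the spread between replicates. With equal list length the Ser2P difference, KD minus control, turned to -701.5 bp, and thinned it was -284.5 bp, so a fall limited to Ser5P was not shown. The Myb promoter itself carried a peak in all 8 libraries.

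Myb lies on the minus strand of chromosome 10, from 21124930 to 21160984, and its enhancers lie between Myb and Hbs1l, which encodes a ribosome rescue factor. In the window 36 kb upstream, Ser5P covered 881 and 783 bp in the controls and 567 and 299 bp in the KD libraries. Ser2P went the other way there, with 335 and 270 bp in the controls and 834 and 393 bp in the deeper KD libraries. The window 61 kb upstream carried both marks in all 8 libraries, with Ser5P coverage of 795 and 792 bp in the controls and 913 and 653 bp in the KD libraries. At 68 kb Ser5P had a peak in control 2 alone, whereas Ser2P had a peak in both controls and in KD 1. The most distant window, with summits about 108 kb upstream, lacked Ser5P in KD 1 only and carried Ser2P in every library. At the 81 kb window Ser2P was present in control 1 and KD 2. Counting both antibodies, 18 of 20 window tests were positive in the controls and 14 of 20 in the KD libraries (exact permutation within antibody over 36 arrangements, p = 0.167; the smallest possible was 0.0556).

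At the Myb promoter Ser5P covered 334 and 432 bp in the controls and 339 and 445 bp in the KD libraries. Ser2P there covered 366 and 215 bp in the controls and 1081 and 1005 bp in the KD libraries (exact permutation p = 0.333). Both KD libraries were the deeper ones and had the wider peaks. Along the Myb transcribed interval Ser2P covered 1527 and 0 bp in the controls and 545 and 945 bp in the KD libraries. The neighbours Hbs1l and Ahi1, a gene of the primary cilium, carried both marks at their promoters in all 8 libraries. No peak of either mark lay within 1000 bp of the outer 5′ end of Sgk1, Pde7b, Mtfr2 or Bclaf1. Peaks inside all 4 of these genes were present in all 8 libraries. A start inside the gene is not seen as a promoter here, so a lack of polymerase at the promoters of these genes was not shown. Aldh8a1, an aldehyde dehydrogenase gene, had a Ser2P promoter peak in control 1 alone.

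**Figure D1:**
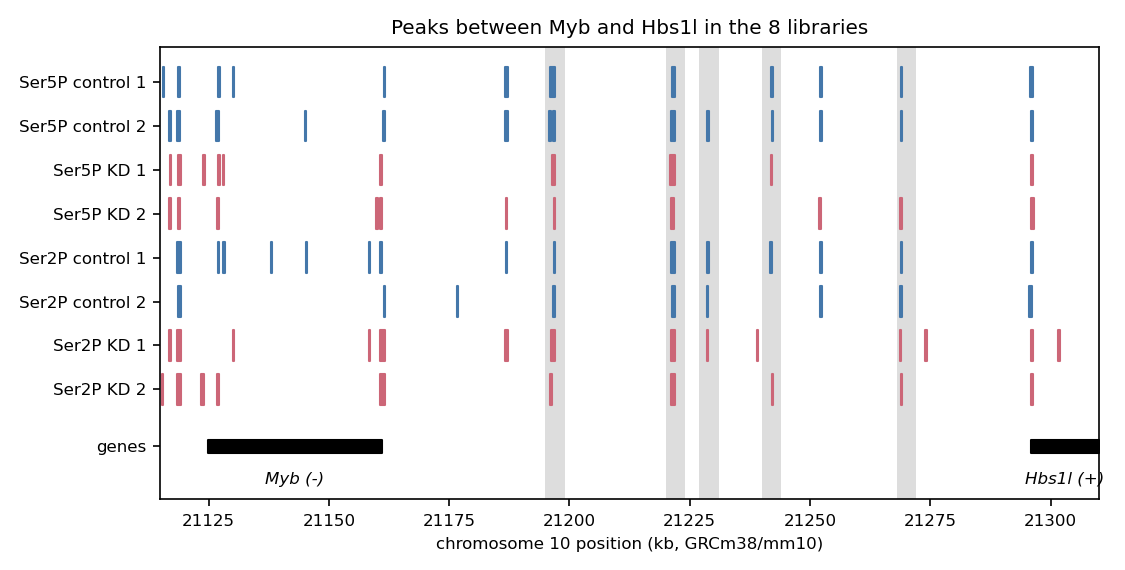
Peaks of the 8 libraries (bars, controls blue, KD red) along chromosome 10 in kb, with the 5 enhancer windows in grey and the genes Myb and Hbs1l in black. Ser5P peaks covered 2456 bp of the windows on average in the controls and 1546 bp in the KD libraries, and the window 61 kb upstream is marked in all 8.

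For Ser5P genome-wide, 1537 regions were control-only and 822 were KD-only, beside 14371 of 37531 regions present in all 4 libraries. At promoters 94 genes were control-only and 87 KD-only, while 7988 genes carried promoter Ser5P in all 4 libraries. The other 2 splits of the libraries gave 1543 and 1394 regions over both directions, against 2359 for control against KD, and 138 and 130 genes, against 181. With equal numbers of peaks per library the counts were 1169 and 940 regions, and 81 and 125 genes. After thinning the gene counts were 120 and 75, so the direction at promoters turned with the peak set.

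The promoters with control-only Ser5P that ranked high by the authors' peak fold included those of Cyp2r1, a vitamin D 25-hydroxylase, Prss42, Rassf4, Tespa1, Cyp4b1, Nedd9 and Gnb4. Dnajc1, a co-chaperone of the endoplasmic reticulum, ranked high too, but the edge of a peak covered only 29 and 26 bp of its promoter window in the controls. Ndufa9, a subunit of respiratory complex I, was control-only as well. In the KD-only direction the leading promoters were those of Pxn, which encodes paxillin, Apba1, and the Mediator subunit gene Med9. Zfp449, Zdhhc17, Tmem245, Zfp493, Klhl8, Zscan22 and Mipep came next. Cdk6, a cyclin-dependent kinase of the G1 phase listed among progenitor genes linked to Myb, was KD-only too. With the stricter threshold Ndufa9, Cdk6 and Zfp493 lost their calls, with thinning Zscan22 did, and with at least 200 bp of the window covered Dnajc1 did. The highest ranked control-only regions lay on chromosome 16 (3121432 to 3121868) and chromosome 17 (70963658 to 70963905), both intergenic, and on chromosome 5 (32015904 to 32016510) within Babam2. The others lay on chromosome 19 (21104448 to 21105210) and at the Cyp2r1 promoter on chromosome 7 (114562555 to 114563303). KD-only regions of highest rank were 3 intergenic ones, on chromosome 18 (85697935 to 85698282), chromosome 13 (24771201 to 24772095, 9.71 kb from the Gmnn 5′ end) and chromosome 11 (58572755 to 58573419), and those within Nav2 (chromosome 7, 49468015 to 49468529) and Dennd1a (chromosome 2, 38259025 to 38259437).

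For Ser2P the balance lay the other way, with 764 regions control-only and 2442 KD-only, and 116 genes control-only and 475 KD-only. The other 2 splits gave 2338 and 1833 regions over both directions, against 3206, and 466 and 334 genes, against 591. This balance changed with the peak set: after thinning to the shallowest library there were 1425 control-only and 951 KD-only regions, and 300 and 250 genes. With equal numbers of peaks per library the counts were 962 and 1188 regions, and 238 and 297 genes.

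Among genes whose Ser2P was control-only, the highest ranks were Ugt8a, which makes galactosylceramide, Bckdhb, a subunit of the branched-chain ketoacid dehydrogenase, and Cobl, an actin nucleator. Phf11b, Mcoln3, Yaf2, Mamdc2, Amn1, Arid5b and Fam171a1 followed. Ccnt1, the cyclin T1 partner of the Ser2 kinase Cdk9, and Sdhd, a subunit of succinate dehydrogenase, were called in the same direction, but Ccnt1 lost its call with the stricter threshold, equal list length and thinning. Among the 10 highest ranked KD-only genes, peaks covered 515 and 764 bp of the window of Erlin1, 370 and 384 bp of that of Mtfr1l, and 241 and 241 bp of that of Cby1 in the KD libraries. The other 7 were Hnrnpul2 (102 and 29 bp), Trim27 (21 and 135 bp), Ntan1 (69 and 415 bp), Phpt1 (15 and 141 bp), Tex261 (21 and 155 bp), Spag7 (12 and 7 bp) and Xrcc2 (91 and 134 bp), where in at least 1 KD library a peak reached less than 200 bp into the window. All 10 leading genes of each direction kept their call with the stricter threshold, equal list length and thinning. With at least 200 bp covered, all 10 control-only genes kept it and only 3 of the 10 KD-only genes did. The highest ranked control-only regions were intergenic, on chromosome 17 (22876315 to 22876531), chromosome 12 (12488099 to 12488578), chromosome 16 (17222266 to 17222524), chromosome 1 (94858473 to 94858888) and chromosome 3 (122704142 to 122704616, 24.8 kb from the Pde5a 5′ end). KD-only regions were led by intergenic ones on chromosome 3 (149052500 to 149052929), chromosome 13 (74563689 to 74564327) and chromosome 11 (86836414 to 86837218), and by the promoters of Ica1l (chromosome 1, 60042522 to 60043306) and Lilra6 (chromosome 7, 3915318 to 3915734).

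**Figure D2:**
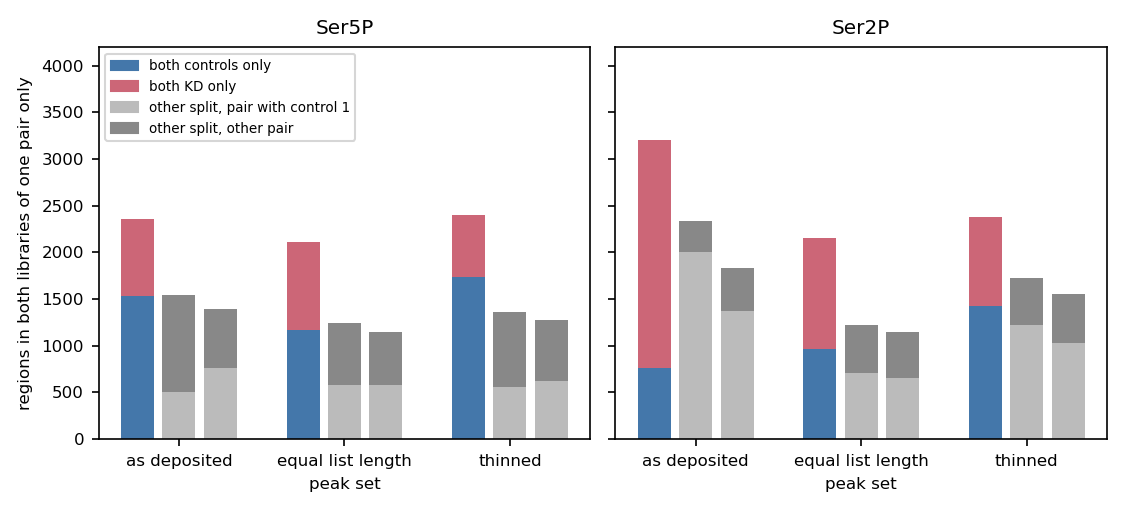
Number of regions found in both libraries of one pair and in neither of the other, for Ser5P and Ser2P, with the peak lists as deposited, cut to equal length or thinned to the shallowest library. Coloured bars are control against KD (2359 regions for Ser5P and 3206 for Ser2P as deposited), and grey bars are the other 2 splits of the same 4 libraries, which were lower in each panel.

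Among the 16 gene lists, DNA replication and cell cycle genes passed the threshold for Ser2P gain: 5 of 18 members unmarked in both controls were marked in both KD libraries, against 4.04% of other genes (Fisher's exact test, adjusted p = 0.0334 over 55 tests). The other genes included many with no Ser2P peak in any library. A peak in at least 1 of the 4 libraries was found for 43 of 51 members and for 10446 of all 20583 genes. Genes that could be called were thus commoner in the list, so the test does not show a gain particular to it. The same limit holds for the other gain tests. The 5 called members were Rrm2, a subunit of ribonucleotide reductase, Birc5, or survivin, Mcm4, a subunit of the replicative helicase, Tpx2, a spindle factor, and Hmmr, which was named after its values were seen. With the stricter threshold 6 of 31 members were called (adjusted p = 0.0170), and the list passed again. With at least 200 bp of the window covered, 3 of 18 members were called (adjusted p = 0.606), without Hmmr and without Rrm2, which had 120 and 133 bp covered. After thinning 2 of 22 members were called (adjusted p = 1.0), and 2 of 23 with equal list length. The adjusted p was 0.107 without control 1, 0.0677 without control 2, 0.108 without KD 1 and 0.000558 without KD 2.

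Of the 12 MLL1 complex genes, which encode a histone H3 lysine 4 methyltransferase and its partners, 11 carried promoter Ser5P in every library. Ser2P was present over 8 and 8 of them in the controls and over 10 and 11 in the KD libraries. Kmt2a, which encodes MLL1 itself (chromosome 9, 44803355 to 44881352), and Psip1, its chromatin tether, were KD-only, 2 of 3 members unmarked in both controls (Fisher's exact test, p = 0.00484, adjusted p = 0.133). Kmt2a kept its call with the stricter threshold, equal list length and thinning, and Psip1 lost it with the stricter threshold and with thinning. No other list passed the threshold in these tests on all libraries. Without control 1, ribosomal protein genes passed for Ser2P gain (adjusted p = 0.0408). Among members unmarked in both controls, those called for Ser2P gain included Rpl6 and Rpsa of 36 ribosomal protein genes, Polr2a of 7 polymerase kinases and elongation factors, Uqcrc2 of 29 respiratory chain genes, and 4 of 42 histone genes (H4c18, H2ac24, H2ac18 and H3c14). The windows of H2ac18 and H3c14 overlap, as do those of H4c18 and H2ac24, so a single peak can mark both. All 4 of these histone genes are shorter than 1000 bp, so their windows lie wholly past their 3′ ends. Ser2P over each gene itself was therefore not measured by its window, and the H2ac18 window holds the H3c14 gene. Polr2a, Rpl6, Rpsa, H2ac18 and H3c14 lost their calls with the stricter threshold, equal list length and thinning, as did Tpx2. Uqcrc2 and Mcm4 lost theirs with the stricter threshold and equal list length, and H2ac24 and Birc5 with thinning.

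Erythroid and haematopoietic regulators were marked by Ser2P in 24 and 23 of 24 in the controls and 23 and 24 in the KD libraries. No member was called in either direction, but none was unmarked in both controls, so a Ser2P gain could not be called. Promoter Ser5P was present at 2 of 13 HOXA-MEIS genes and at 28 of 38 immediate-early and stress genes in all 4 libraries, with no member called for either antibody. Of the markers of other cell types, promoter Ser5P was present in all 4 libraries at 0 of 20 lymphoid, 0 of 20 non-haematopoietic, 3 of 20 myeloid and 3 of 19 megakaryocyte and mast cell markers. Ser2P over the transcribed interval was present in all 4 libraries at 6 of 20 lymphoid, 4 of 20 non-haematopoietic, 6 of 20 myeloid and 6 of 19 megakaryocyte and mast cell markers. No marker of these 4 lists was called in either direction. Calls were rare among other genes as well, with 1.12% lost and 0.77% gained for Ser5P and 1.92% lost and 4.08% gained for Ser2P. The absence of calls in lists of this size therefore decides little.

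The last comparison set the antibodies against each other. On average 33.2% ± 1.91 of Ser5P summits and 29.0% ± 4.14 of Ser2P summits lay within 1000 bp of a gene 5′ end (SD, n = 4 each), a difference of 4.21 percentage points that did not pass the test (two-sided exact permutation p = 0.114). Within the controls the difference was 1.05 points and within the KD libraries 7.38 points. Ser2P control 2, the shallowest library, stood at 35.1% and the other Ser2P libraries between 26.0% and 27.6%. Promoter Ser5P in all 4 libraries was found at 7988 genes, and 39.6% of these carried Ser2P over the transcribed interval in all 4 libraries, against 19.1% of other genes. With the same number of peaks from every library, the shares were 36.8% ± 0.265 and 35.9% ± 0.693 (SD, n = 4 each; exact permutation p = 0.0857).

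**Figure D3:**
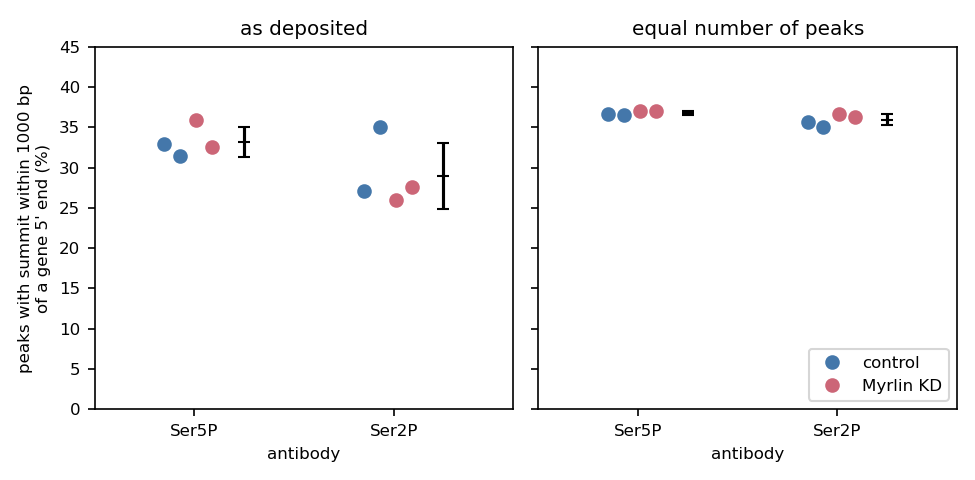
Percent of peaks with the summit within 1000 bp of a gene 5′ end, per library (points, controls blue, Myrlin KD red) with mean and SD (n = 4), for the lists as deposited and for equal numbers of peaks. As deposited the means were 33.2% for Ser5P and 29.0% for Ser2P, and with equal numbers 36.8% and 35.9%.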

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

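Thinning, the 200 bp minimum for named genes and lists, and all values of the ratios and joint regions were chosen after seeing the data. With −log10 q of at least 5, region counts fell to 505 (Ser5P KD-only), 451 (Ser2P control-only) and 1422 (Ser2P KD-only). At equal list length Ser2P gave 1188 KD-only regions, and 238 control-only and 297 KD-only genes. Thinned, it gave 1425 and 951 regions and 300 and 250 genes. The ratio of control-only to KD-only regions was 1.24 for Ser5P and 0.810 for Ser2P at equal length, which draws it towards 1 by construction, and the Ser2P ratio turned to 1.5 when thinned (1.46 to 1.61 over 20 draws). Thinned joint regions numbered 218 control-only and 36 KD-only. Thinning removes more peaks from deeper libraries, which by itself pulls the Ser2P KD-only counts down. The cause was not tested for the other changes. Without the gene extension Ser2P called 76 and 295 genes, and 73 control-only genes around 3′ ends. For Ser2P at the Myb enhancer windows, the KD minus control difference was -701.5 bp with the stricter threshold, -701.5 bp at equal length and -284.5 bp thinned.

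The replicate numbers did not pair the samples: the labels give no shared batch, and deviations of same-numbered libraries correlated at 0.0356 (Ser5P) and 0.0952 (Ser2P) across genes. Limma on covered shares called 0 genes in each direction for both antibodies (adjusted p under 0.05), and 0 with the replicate block. The power of limma for changes that real shares can take was not measured. At an unadjusted p under 0.05 it called 210 and 643 genes for Ser5P (control and KD higher) and 63 and 959 for Ser2P. Peaks were wider in every KD library for both antibodies, which raises covered shares throughout. These counts therefore do not show a gain at particular genes. Gene lists past the threshold numbered 0 at equal length, 0 thinned and 0 with at least 200 bp covered, against 1. With the replicate block (Cochran-Mantel-Haenszel) they numbered 7: for Ser2P gain cell cycle, MLL1 (adjusted p = 0.00808), ribosomal (0.00876) and polymerase genes (0.00338), for Ser5P gain polymerase and respiratory genes, and for Ser2P loss respiratory genes. In this test the same gene can enter once per replicate number, although such calls are not independent, which lowers p. These 7 results therefore add no support beyond the main tests.

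Leaving out each library leaves a single library in a group, which raises counts by construction. Ranges were 2420 to 5615 control-only and 1534 to 4907 KD-only regions for Ser5P, 1325 to 6586 and 3128 to 9561 for Ser2P, 207 to 281 and 179 to 280 Ser5P genes, and 262 to 600 and 643 to 1727 Ser2P genes. The easier rule for that group also moves the ratio its way by construction, so its range (0.493 to 3.66 for Ser5P, 0.139 to 2.11 for Ser2P) says nothing of direction, including the values below 1 for Ser5P without KD 1 (0.493) or KD 2 (0.935) and above 1 for Ser2P without control 2 (2.11). Joint regions ranged from 162 to 298 and from 129 to 305, lists past the threshold from 0 to 1, and the Myb window differences from -1119.5 to -700.5 bp (Ser5P) and -102.5 to 536.5 bp (Ser2P). The promoter share difference ranged from 3.23 to 6.26 points and stayed on its side of the threshold in all alternatives. Starts of annotated transcripts were not run, since transcripts of this build were not used here. Of the named calls, 43 of 236 tests under other peak sets or the 200 bp minimum were lost. None could turn round, since these settings only remove peaks or coverage.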

Other observations

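All tests in this part were chosen after the data had been seen, and the bounds for the depth test of Ser2P and the main ratio of Jaccard indices were set before those values were computed. Regions that lost or gained both marks were collected by merging the peaks of all 8 libraries. Of 56005 regions, 129 had a peak in every control library and in no KD library, and 103 the reverse. The first set was led by an intragenic region of Phf11b on chromosome 14 (59322334 to 59323886), an intergenic region 24.8 kb from Pde5a, which encodes a cGMP phosphodiesterase, and a region within Rpa1. It also held the promoters of Cyp2r1 and Rassf4. The KD-only set was led by regions within Panx1, a channel gene, and Ccdc30, and held the promoters of Polr2m and Glipr1. Regions that were control-only for both antibodies numbered 129 where independent lists would share 20.8. Regions KD-only for both numbered 103 where 34.5 would be shared. The opposite combinations numbered 58 (Ser5P control-only, Ser2P KD-only) and 2, where 65.7 and 10.9 would be shared. Independence is not the value without a group difference, since other splits of the libraries gave up to 92 shared regions in a single direction.

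Called regions also differed in place. For Ser5P, 13.5% of KD-only regions overlapped a promoter window (95% Wilson interval 11.3 to 16.0) against 8.0% of control-only regions (6.75 to 9.47; Fisher's exact test, odds ratio 1.79, adjusted p = 6.9e-05). For Ser2P the shares were 11.5% (10.3 to 12.9) and 6.81% (5.23 to 8.82; odds ratio 1.79, adjusted p = 0.000136). At equal list length the Ser2P shares were 19.1% and 7.28% (odds ratio 3.01), and thinned they were 18.0% and 10.0% (odds ratio 1.97). In the other splits of the Ser5P libraries the shares were 12.7% and 10.5%, and 11.8% and 11.4%. For Ser2P they were 9.10% and 6.82%, and 8.27% and 9.66%. Regions are not replicates, so these p-values compare the libraries at hand. KD-only regions were also wider than control-only ones, with medians of 503 against 469 bp for Ser5P and 502.5 against 401.5 bp for Ser2P. At equal list length the Ser2P medians were 571 and 431.5 bp. A wider region overlaps a promoter window more easily, and the shares were not adjusted for width.

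Between the Myb and Hbs1l promoters, a stretch of 133 kb, Ser5P peaks covered 3409 ± 89.1 bp in the controls and 1923 ± 237 bp in the KD libraries (SD, n = 2 each), a ratio of 0.564. Of 2850 windows of that length with between 0.5 and 2 times that control coverage, 67 (2.35%) had a ratio as low, and the median ratio was 0.99. In 19.1% of these windows both KD libraries lay below both controls. The windows were chosen by length and control coverage, whereas the Myb interval leaves out the promoters at both ends. The rank was also chosen after seeing the data, so 2.35% is not a p-value. For Ser2P the Myb ratio was 1.09 against a median of 1.39, and 14.7% of 3538 like windows were as low. A site about 91.2 kb upstream of Myb, outside the fixed windows, carried Ser2P in both controls and neither KD library, and Ser5P in all but KD 1.

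The excess of Ser2P KD-only regions went with depth. The prediction was that thinning would bring the ratio of KD-only to control-only regions to at most 1.5, and it fell to 0.667. Thinning left 66.0% and 69.5% of the Ser2P KD peaks against 81.2% and 100% of the control peaks. It therefore lowers the ratio whatever the cause of the excess. Deeper KD libraries could account for the excess, but the value of 0.667 does not decide. Shallower KD libraries, as a reason for the opposite excess for Ser5P, would have needed a lower background pileup in the KD libraries. It was 0.649 and 0.841 there against 0.566 and 0.639 in the controls, with KD 1 close to control 2, so this condition was not met. The ratio of control-only to KD-only regions was 2.64 after thinning. Thinning left 97.4% and 89.3% of the KD peaks against 100% and 97.7% of the control peaks. It could therefore hardly lower the ratio, and the value of 2.64 does not decide. Shorter or less enriched KD peak lists stay open: at equal list length the ratio was 1.24, but equal lists bring the directions towards balance by construction, so this value does not decide. An effect of Myrlin knockdown on Ser5P stays open and was not separated from differences in enrichment between libraries.

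The regions joint to both antibodies numbered 232 over both directions. Among the 18 ways to split the libraries in pairs within each antibody, 1 gave as many, the real one, and the highest other gave 96; 18 splits are too few for a share under 0.05. Copy-number or deletion differences between the cell lines may contribute: neighbours within 1 Mb numbered 20 for control-only and 14 for KD-only regions, 34 in all, where random draws had medians of 13 and 8, and the upper ends of their central 95% were about 20 and 14. These counts sit at the upper ends, so the explanation cannot be told apart from an effect of the knockdown, and single small deletions would not have been seen by this test. After thinning, 218 control-only and 36 KD-only joint regions were counted.

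Whether Ser5P and Ser2P peaks lay at the same places was left undecided. The median Jaccard index of covered bp was 0.472 between antibodies and 0.521 between libraries of the same antibody, a ratio of 0.906, where at least 0.9 had been predicted if both antibodies draw mainly promoter and enhancer chromatin. Leaving out each library gave ratios from 0.882 (without Ser2P control 1) to 0.970, on both sides of that bound, and 0.898 without Ser2P control 2, the shallowest. Every pair of Ser5P libraries (0.526 to 0.558) exceeded every pair between antibodies (at most 0.493), while Ser2P pairs ranged from 0.381 to 0.517. No biological explanation was tested for this pattern.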
